A study of Mus musculus with 24 samples.

How the data were processed

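RNA of 24 mouse aortas was sequenced, in 8 groups of 3 libraries that cross genotype (wild type or Cthrc1 knockout), treatment (PBS or Ang-II/BAPN) and title set (titles that start with F or do not). Genotype and treatment come from the labels, and replicate numbers from the titles. Per the labels' protocols, libraries were made from total RNA with a stranded total RNA kit and read as paired ends on an Illumina HiSeq sequencer. Nothing in the labels says which animals, litters or days the libraries share, so that p-values measure only the spread between these samples, which may be technical.

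The authors deposited 1 table of 40141 Ensembl genes with a whole-number count and an FPKM value per library. Per the submitters' processing notes HISAT2, StringTie, DESeq2 and build GRCm38 were used, without versions or roles. How the deposited counts were made, whether the counting used strand, and how reads of paralogs and overlapping genes were split are not given in the sources used here. Without knowledge of the strand setting, counts of a gene and its antisense partner cannot be told apart. FPKM values, named so in the file's headers, were used in 1 alternative analysis. The table also holds 4 columns of 2 libraries that the labels used here do not describe, and these columns were used in no step. Gene positions are those of the table. Of its gene identifiers, 39991 were also in the GENCODE M21 annotation of the same build, 92.3% of them with the same start and end. GC content and transcript length came from that annotation.

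Total counts per library ran from 39.0e6 to 82.0e6. Mitochondrial genes took 9.6 to 31.9% of the counts of a library, and the 10 most abundant genes of a library 10.7 to 33.3%. Replicates correlated at 0.959 to 0.992 over log2 CPM. The chi-square per degree of freedom between replicates was at least 61.9, so that no pair of libraries agreed within sampling noise. Precision was set by the spread between libraries, with a common biological coefficient of variation of 57%. Floors for genes without counts are 3 counts pooled over a group and cover counting error only, not the spread between libraries.

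Counts were tested with edgeR 4.0.16 in R 4.3.3. The function filterByExpr on the 8 groups (minimum count 10, minimum total 15) kept 24623 genes and left out 15518. TMM normalisation and a robust quasi-likelihood fit with 8 group means followed. Comparisons were contrasts of these means, averaged over the title sets and also taken within each set, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are in CPM, counts scaled to equal library size with TMM factors. They are given as mean ± SD over the 6 libraries of a genotype and treatment. The levels of Xist, Ddx3y, Rn7sk, Hbb-bs and Acta2 in single libraries were scaled to the total count without TMM factors. Fold changes are log2 values with a standard error derived from the F statistic. The 403 members of 30 gene lists were all tested. The list tests were limma 3.58.1's camera at a preset correlation of 0.01 on log2 CPM (prior count 2), camera at an estimated correlation and fry, each adjusted over the lists of a comparison. Counts of list members are also given after adjustment over the list alone.

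The named genes were fixed by a rule. In every comparison they are Cthrc1 and, among called genes, the 6 with the largest rise and the 6 with the largest fall. These have 1 sign in both title sets, a mean of at least 2 CPM and a named symbol. The rule adds up to 4 members per list with the smallest adjusted p (where fewer than 2 passed, the first 2 tested). The rule also takes the genes next to Cthrc1. Some genes it gives are not reported here. Xist, Ddx3y and Ly6g come from the lists. Slc34a1, Rn7sk, Nnt, Hbb-bs and the marker genes of other organs were chosen after their values were seen. The groups, tests, gene lists, this rule and the first set of alternatives were chosen before the data were examined.

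The test was checked on 1 set of simulated counts for the 24623 genes, with each gene's mean level over all libraries, its dispersion and the real library sizes. Of genes at 1 CPM or more, 200 were changed in treated knockout and 200 others in treated wild type libraries, by 1.5, 2 or 4-fold up or down. Changes of 4-fold were recovered for 81.8% of genes in the wild type response, 80.3% in the knockout response, 85.6% between treated genotypes and 59.8% in the interaction. Changes of 2-fold were recovered for 35.8%, 38.8%, 41% and 13.4%, and false calls were 4.5%, 3.5%, 2.1% and 9.1% of all calls.

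Alternatives were RLE size factors, DESeq2 1.42.0, limma on log2(FPKM + 1), no filter, a stricter filter and a replicate block. Others were models without the title set or with it as an added term, only the libraries compared, a fold change of at least 2, and leaving out each library in turn. Added after seeing the data were fits without 5 libraries with high Rn7sk, with that class as a covariate, and without mitochondrial and ribosomal RNA genes. Further added were fits with the spread estimated per treatment, and DESeq2 on the 12 treated libraries. Marker levels of intestine and pancreas also served as covariates, and the F set was fitted without its 2 libraries that hold intestinal transcripts. These marker levels partly follow genotype and treatment, so that a fit with them cannot separate organ RNA from either. Correlations and chi-square values between replicates were computed with numpy 2.4.6 in Python 3.11.15, where the deposited table was read with pandas 2.3.3. The other correlations and the permutations were run in R. Figures were drawn with matplotlib 3.10.9. Camera was also run on 297 KEGG pathways as the table annotates them, and these tests are left out of the text. Exon-level signal and reads were not analysed here.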

Results

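Total RNA of mouse aorta was sequenced to ask how the loss of Cthrc1 changes the vessel in a model of aortic dissection. Cthrc1 encodes a secreted protein with a collagen triple helix repeat that is made by injured arteries. Animals received phosphate-buffered saline (PBS) or Ang-II/BAPN, that is angiotensin II, which raises blood pressure, with β-aminopropionitrile, an inhibitor of the lysyl oxidases that cross-link elastin and collagen. The 24 libraries made 8 groups of 3, which crossed genotype (wild type or Cthrc1 knockout), treatment and title set. A title set holds the libraries whose titles start with F (the F set) or do not (the plain set), and the labels do not say what F stands for. Mitochondrial genes took 9.6 to 31.9% of the counts. Xist, the RNA of the inactive X chromosome, lay between 188 and 1020 CPM (counts scaled to equal library size) in the F set and between 0.139 and 14.5 CPM in the plain set. Ddx3y, a gene of the Y chromosome, lay between 0 and 1.32 CPM in the F set and between 43.5 and 118 CPM in the plain set.

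Cthrc1 (ENSMUSG00000054196; GRCm38 chromosome 15, positions 39076932 to 39087121, plus strand) was the targeted gene and was examined first. Under PBS its level was 1.87 ± 0.378 CPM in wild type and 0.366 ± 0.175 CPM in knockout aorta (SD, n = 6 each). Under Ang-II/BAPN it was 69 ± 32.7 CPM in wild type and 4.97 ± 3.21 CPM in knockout aorta (SD, n = 6 each), and the highest knockout library (10.5 CPM) lay below the lowest wild type library (26.5 CPM). Knockout libraries held 7.21% of the wild type level under Ang-II/BAPN. Cthrc1 rose with treatment in wild type aorta (log2 fold change 5.19, SE 0.45, edgeR adjusted p = 8.06e-07) and, from a lower start, in knockout aorta (log2 fold change 3.71, SE 0.44, edgeR adjusted p = 2.27e-05). It was lower in knockout than in wild type aorta under Ang-II/BAPN (log2 fold change -3.83, SE 0.42, edgeR adjusted p = 0.000491), with values of -3.99 in the plain set and -3.66 in the F set. Under PBS the difference of -2.35 (SE 0.42) missed the threshold (edgeR adjusted p = 0.18). The counts are per gene, so that they do not show which exons the remaining knockout counts came from. The neighbouring genes Baalc, Fzd6, Slc25a32, Dcaf13, Rims2 and Dcstamp did not pass the test between genotypes under either treatment. The call under Ang-II/BAPN was lost in 3 of 28 alternative analyses (adjusted p up to 0.486). Log2 fold changes ran from -4.51 to -3.46 over all 28.

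**Figure D1:**
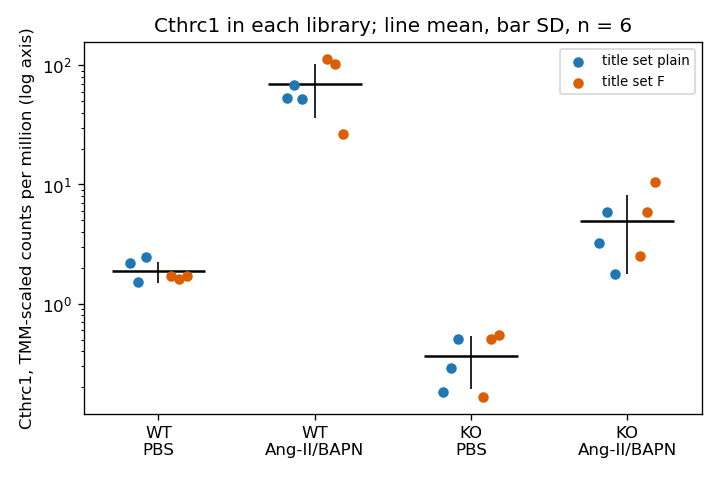
Cthrc1 in CPM (log axis) for each of the 24 libraries, by genotype and treatment; lines are the mean of each group and bars 1 SD (n = 6). Treated wild type libraries lie between 26.5 and 112 CPM and treated knockout libraries between 1.79 and 10.5 CPM.

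The first comparison asked what Ang-II/BAPN did to wild type aorta. Treatment changed 6097 of 24623 tested genes, 3277 higher and 2820 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 6 per group). Genes of macrophages, neutrophils, chemokines, the cell cycle and matrix turnover rose, and smooth muscle contractile genes fell. All 17 contractile genes fell, also adjusted over the list alone (median log2 fold change -2.11; camera adjusted p = 4.02e-15, and adjusted p = 0.0999 with an estimated correlation). Myl9, the regulatory light chain of smooth muscle myosin, went from 3200 ± 927 to 472 ± 192 CPM (log2 fold change -2.74, SE 0.34, edgeR adjusted p = 1.11e-05). Smtn, which encodes the actin-binding protein smoothelin of contractile cells, fell by 2.24 on the log2 scale (SE 0.23, edgeR adjusted p = 1.84e-06). Pln, the regulator of the calcium pump of the sarcoplasmic reticulum, fell by 2.8 (SE 0.31, edgeR adjusted p = 4.4e-06).

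Of 18 macrophage markers, 17 rose, and 18 adjusted over the list alone (median 3.28; camera adjusted p = 7.63e-18, and adjusted p = 0.0542 with an estimated correlation). Cd68, a lysosomal glycoprotein of macrophages, went from 6.94 ± 1.64 to 82 ± 75.7 CPM (log2 fold change 3.42, SE 0.33, edgeR adjusted p = 1.34e-06). Trem2, a lipid receptor of macrophages, rose by 4.5 (SE 0.47, edgeR adjusted p = 2.17e-06). Of 10 neutrophil markers, 8 rose, and 9 adjusted over the list alone (median 4.91, or 4.79 with Ly6g, which had no count under PBS, at its bound; camera adjusted p = 9.12e-09, and adjusted p = 0.0542 with an estimated correlation). The chemokine receptor gene Cxcr2 went from 0.21 ± 0.161 to 15.1 ± 9.32 CPM, and S100a9, a calcium-binding protein of neutrophil granules, from 0.636 ± 0.527 to 24.3 ± 20.3 CPM (edgeR adjusted p = 8.35e-06 and 2.24e-05). Of 19 inflammatory cytokines and chemokines, 18 rose, and 19 adjusted over the list alone (median 4.42; camera adjusted p = 1.62e-13, and adjusted p = 0.0999 with an estimated correlation). Ccl2, which attracts monocytes, rose by 5.12 (SE 0.69) and Cxcl1, which attracts neutrophils, by 3.66 (SE 0.49).

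All 12 T cell markers and all 10 B cell and plasma cell markers rose in treated wild type aorta, also adjusted over each list alone (medians 2.44 and 2.88; camera adjusted p = 2.8e-06 and 0.000192). Neither kept its call with an estimated correlation (adjusted p = 0.284 and adjusted p = 0.31 with an estimated correlation). Il7r, the receptor of interleukin 7, rose by 4.1 (SE 0.64) and Cd4, the coreceptor of helper T cells, by 2.92 (SE 0.54). Jchain, which links immunoglobulin multimers in plasma cells, went from 1.09 ± 1.13 to 22.2 ± 14.3 CPM, and Ms4a1, which encodes the B cell antigen CD20, from 0.698 ± 0.681 to 11.1 ± 13.6 CPM (edgeR adjusted p = 0.00143 and 0.003). On leaving out replicate 1 of the treated F set the medians were 2.1 and 1.76 with 7 and 5 genes called, and without the 5 libraries with high Rn7sk 5 and 3 genes were called. In the same treated wild type group, 7 of 10 intestinal marker genes were higher than under PBS. Summed Clca1, Agr2, Car1, Lypd8 and Cyp2c55 reached 188, 211 and 110 CPM in its plain set and 75 CPM in replicate 2 of its F set, against at most 1.83 CPM in its other libraries.

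Of 20 cell cycle genes, 19 rose, also adjusted over the list alone (median 2.7; camera adjusted p = 2.2e-14, and adjusted p = 0.148 with an estimated correlation). The proliferation marker Mki67 went from 7.87 ± 5.67 to 63.1 ± 20.3 CPM (log2 fold change 3.19, SE 0.39, edgeR adjusted p = 9.37e-06). Of 16 interferon-stimulated genes 14 rose, and of 11 antigen presentation genes 8 rose, with the same counts adjusted over each list alone (medians 1.65 and 1.74; camera adjusted p = 3.23e-06 and 4.68e-06, and adjusted p = 0.308 and adjusted p = 0.284 with an estimated correlation). Mx1, an antiviral GTPase, rose by 3.48 (SE 0.51), and H2-Aa, a chain of the major histocompatibility complex class II, by 2.07 (SE 0.29).

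Matrix genes moved upward in wild type aorta. Of 19 matrix proteases 13 rose and 1 fell, and adjusted over the list alone 15 rose and 1 fell (median 1.5; camera adjusted p = 1.24e-07, and adjusted p = 0.0542 with an estimated correlation). Mmp12, the macrophage elastase, went from 0.29 ± 0.154 to 8.96 ± 5.5 CPM, Ctss, an elastin-degrading cathepsin, from 10.1 ± 2.63 to 307 ± 201 CPM, and the stromelysin gene Mmp3 from 21.8 ± 7.25 to 125 ± 41.5 CPM (edgeR adjusted p = 4.86e-06, 5.99e-07 and 1.42e-05). Of 25 matricellular and fibrosis genes 13 rose, and adjusted over the list alone 17 rose and 1 fell (median 0.83; camera adjusted p = 9.69e-08, and adjusted p = 0.0999 with an estimated correlation). Timp1, an inhibitor of metalloproteases, rose by 5.09 (SE 0.54), and Thbs1, the matricellular protein thrombospondin 1, by 3.62 (SE 0.48). Of 15 collagens 7 rose and 1 fell, also adjusted over the list alone (median 0.53; camera adjusted p = 0.000391, and adjusted p = 0.378 with an estimated correlation). The collagen median was 0.25 without the 5 libraries with high Rn7sk, and with the organ covariates it was 0.48 with 4 genes higher, both chosen after seeing the data. Col12a1 rose by 3.49 (SE 0.38), and Col3a1, a main fibrillar collagen of arteries, went from 3020 ± 1590 to 8980 ± 1440 CPM. Of 19 elastic fibre genes 9 rose and 3 fell, also adjusted over the list alone (median 0.54; camera adjusted p = 0.0312, and adjusted p = 0.421 with an estimated correlation). Lox and Loxl2, lysyl oxidase genes whose products BAPN inhibits, rose by 2.62 (SE 0.36) and 2.04 (SE 0.28). Of 12 chondrocyte and bone genes 7 rose, also adjusted over the list alone (median 2.41; camera adjusted p = 0.000371, and adjusted p = 0.0542 with an estimated correlation), among them the transcription factors Runx2 (2.8, SE 0.28) and Sox9 (2.0, SE 0.29).

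Several lists moved downward with treatment in wild type aorta. Of 12 endothelial markers 7 fell and 1 rose, and adjusted over the list alone 9 fell and 1 rose (median -0.59; camera adjusted p = 0.0029, and adjusted p = 0.378 with an estimated correlation). The endothelial median was -0.21 without the 5 libraries with high Rn7sk, an analysis chosen after seeing the data, with 2 genes lower, and 2 were lower with the organ covariates. In the former the brown adipocyte median was -0.91 with 3 genes lower, and 0 fatty acid oxidation and 2 respiratory chain genes were lower. Nos3, the endothelial nitric oxide synthase, went from 66.4 ± 17.4 to 35.6 ± 7.1 CPM, and Vwf, the von Willebrand factor gene, from 189 ± 48.4 to 83.7 ± 32.3 CPM. Of 10 brown adipocyte genes 5 fell, and 6 adjusted over the list alone (median -1.55; camera adjusted p = 0.00192, and adjusted p = 0.284 with an estimated correlation), and Prdm16, a regulator of brown fat identity, fell by 2.02 (SE 0.24). Of 14 respiratory chain genes 6 fell, and 9 adjusted over the list alone, and of 12 fatty acid oxidation genes 4 fell, also adjusted over the list alone (medians -0.55 and -0.5; camera adjusted p = 0.000371 and 0.00879, and adjusted p = 0.378 and adjusted p = 0.451 with an estimated correlation). Cox5a, a subunit of cytochrome c oxidase, fell by 0.93 (SE 0.2), and Cpt1b, which carries fatty acids into muscle mitochondria, fell by 1.86 (SE 0.46). Of 12 clock genes 6 fell and 2 rose, and adjusted over the list alone 7 fell and 2 rose (median -1.49; camera adjusted p = 0.0426, and adjusted p = 0.378 with an estimated correlation). The clock output gene Dbp went from 195 ± 126 to 10.6 ± 9.88 CPM and the repressor gene Nr1d1 fell by 2.62 (SE 0.43), while the activator gene Arntl rose by 1.9 (SE 0.38). In knockout aorta edgeR called 0 of 12 clock genes for treatment, with Dbp at 25.3 ± 29.1 CPM under PBS and 14.1 ± 9.16 CPM treated. The hour of collection cannot be told apart from treatment in this wild type comparison. Of 12 endoplasmic reticulum stress genes 8 rose and 1 fell, also adjusted over the list alone (median 0.92; camera adjusted p = 0.00935, and adjusted p = 0.378 with an estimated correlation), among them the chaperone gene Hspa5 (1.07, SE 0.23).

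Lists without a call as a whole held single genes that changed in wild type aorta. Of 12 fibroblast markers 3 rose and 3 fell (camera adjusted p = 0.818), with Lum, a proteoglycan that binds collagen fibrils, up by 2.22 (SE 0.34) while Clec3b, the tetranectin gene, fell by 3.05 (SE 0.55). Of 17 Wnt pathway genes 5 rose and 2 fell (camera adjusted p = 0.307), and the median of -0.13 became 0.2 on deposited FPKM values. Nkd1, a negative feedback regulator of Wnt signalling, fell by 2.4 (SE 0.25), and Ror2, a receptor of noncanonical Wnt ligands, rose by 2.11 (SE 0.29).

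The largest rises by the naming rule were Lypd8, Trem1, Car1, Mefv, Cd300lf and Mmp8. Lypd8, a protein of the colon epithelium, was at least 3030-fold higher, and Trem1, a receptor that amplifies myeloid inflammation, at least 1030-fold higher, since neither had a count under PBS (floor of 3 counts over the group, counts pooled over its libraries; edgeR adjusted p = 0.00236 and 6.64e-06). Car1, a carbonic anhydrase abundant in colon and red cells, went from 0.0578 ± 0.109 to 35.2 ± 33.5 CPM. The myeloid genes Mefv, Cd300lf and Mmp8 rose by 9.88 (SE 1.32), 9.79 (SE 0.98) and 8.83 (SE 1.11). The largest falls were Gkn3 (-5.21, SE 0.49), Klk10 (-5.15, SE 0.67), Tcap (-4.99, SE 0.88), Cytl1 (-4.22, SE 0.5), Dbp (-4.22, SE 0.64) and Stum (-3.9, SE 0.43). The test called 2120 genes in the plain set and 3430 in the F set alone, and the fold changes of the sets correlated at 0.39 over all tested genes. With the organ covariates the medians of the matricellular, T cell, B cell, interferon, endoplasmic reticulum stress and clock lists were 1.45, 3.92, 4.85, 2.62, 1.78 and -2.92, and that of the respiratory chain list was -0.11 with 0 genes called by edgeR. With deposited FPKM values and limma the split was 5090 higher and 1495 lower. In the F set alone without the 2 libraries that hold intestinal transcripts, an analysis chosen after seeing the data, the count was 984.

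**Figure D2:**
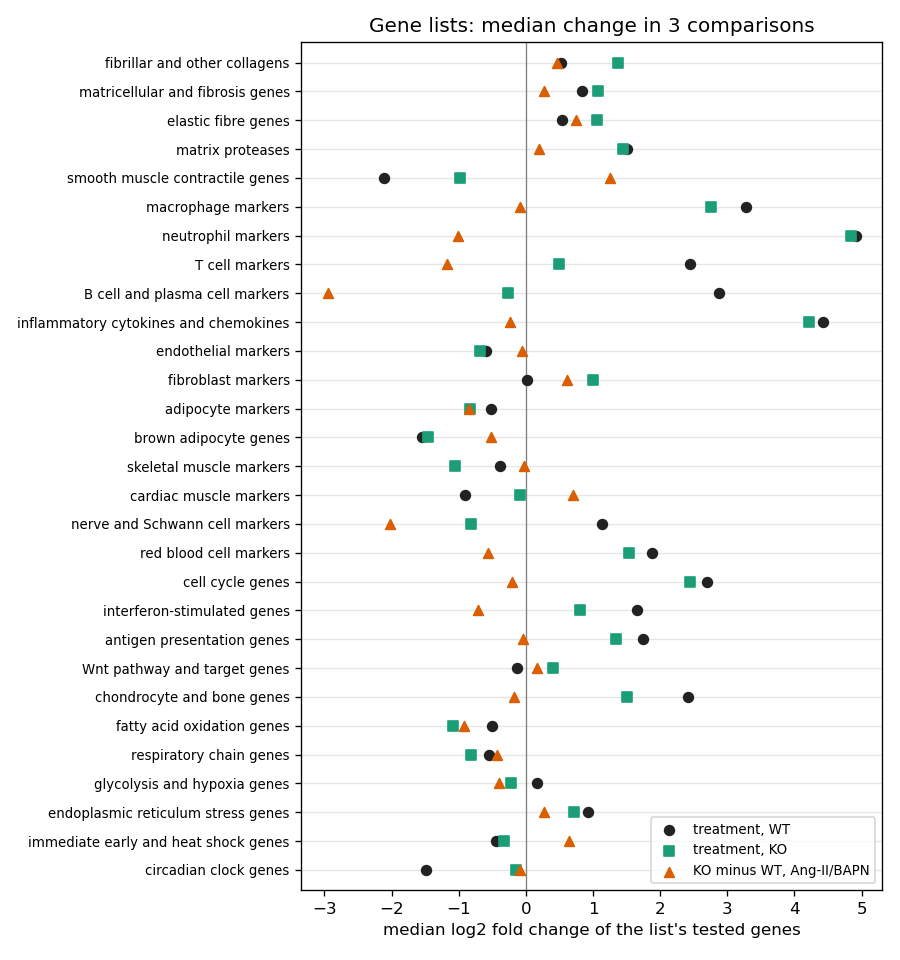
Median log2 fold change of 29 gene lists for Ang-II/BAPN against PBS in wild type, the same in knockout, and knockout against wild type under Ang-II/BAPN. The contractile list lies at -2.11, -0.98 and 1.26 and the macrophage list at 3.28, 2.76 and -0.08; on deposited FPKM values the skeletal muscle list and the Wnt list change sign.

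The second comparison asked the same of Cthrc1 knockout aorta. Treatment changed 2813 genes, 1730 higher and 1083 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 6 per group). Matrix genes, macrophage and neutrophil markers, cytokines and cell cycle genes rose, and contractile, fatty acid oxidation and respiratory chain genes fell. The genes called in both genotypes in the same direction were 1426 of those higher and 562 of those lower, where independent lists would share 230 and 124. Of the genes called in knockout, 2 higher and 8 lower were called in the opposite direction in wild type.

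Of 25 matricellular and fibrosis genes 15 rose, and 19 adjusted over the list alone (median 1.08; camera adjusted p = 2.41e-13, and adjusted p = 0.023 with an estimated correlation). Ltbp2, a matrix protein related to fibrillins, went from 73.9 ± 12.6 to 443 ± 136 CPM (log2 fold change 2.59, SE 0.22, edgeR adjusted p = 1.68e-06) and Timp1 from 14.2 ± 5.38 to 292 ± 205 CPM. Of 19 matrix proteases 14 rose, and adjusted over the list alone 16 rose and 1 fell (median 1.45; camera adjusted p = 2.9e-11, and adjusted p = 0.0214 with an estimated correlation). Mmp12 rose by 4.87 (SE 0.56) and Ctss by 3.69 (SE 0.39). Of 19 elastic fibre genes 11 rose, and 13 adjusted over the list alone (median 1.06; camera adjusted p = 2.92e-09, and adjusted p = 0.0445 with an estimated correlation), with the fibulin gene Fbln2 up by 1.66 (SE 0.2). Of 15 collagens 9 rose, and 11 adjusted over the list alone (median 1.37; camera adjusted p = 4.16e-11, and adjusted p = 0.0679 with an estimated correlation), with Col12a1 up by 3.18 (SE 0.38). Of 12 fibroblast markers 7 rose, and adjusted over the list alone 8 rose and 1 fell (median 1.0; camera adjusted p = 0.00129, and adjusted p = 0.166 with an estimated correlation), among them Lum (2.17, SE 0.34) and the dermatopontin gene Dpt (1.18, SE 0.29). Without the 5 libraries with high Rn7sk the fibroblast median was 0.63 with 2 genes higher and 2 lower, and with the organ covariates 1.07 with 4 higher. Of 12 chondrocyte and bone genes 5 rose, and 7 adjusted over the list alone (median 1.5; camera adjusted p = 0.00111, and adjusted p = 0.0577 with an estimated correlation), with Runx2 up by 2.74 (SE 0.28).

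Of 18 macrophage markers 17 rose in knockout aorta, also adjusted over the list alone (median 2.76; camera adjusted p = 5.65e-25, and adjusted p = 0.0214 with an estimated correlation). Cd14, a coreceptor for bacterial lipopolysaccharide, went from 5.84 ± 2.02 to 40 ± 13 CPM, and Ccr2, the receptor of Ccl2, from 4.8 ± 2.07 to 94.6 ± 44.3 CPM (edgeR adjusted p = 1.41e-05 and 1.44e-05). Of 10 neutrophil markers 8 rose, and 10 adjusted over the list alone (median 4.84, or 4.59 with Ly6g at its bound; camera adjusted p = 3.1e-11, and adjusted p = 0.023 with an estimated correlation). Csf3r, the receptor of granulocyte colony-stimulating factor, rose by 4.25 (SE 0.47) and S100a9 by 4.89 (SE 0.67). Of 19 cytokines and chemokines 18 rose, also adjusted over the list alone (median 4.21; camera adjusted p = 2.13e-17, and adjusted p = 0.0553 with an estimated correlation), with Cxcl1 up by 4.0 (SE 0.5). Of 20 cell cycle genes 18 rose, and 20 adjusted over the list alone (median 2.45; camera adjusted p = 2.76e-19, and adjusted p = 0.0679 with an estimated correlation), with Mki67 up by 2.94 (SE 0.38). Of 16 interferon-stimulated genes 4 rose, and 8 adjusted over the list alone, with Mx1 up by 3.05 (SE 0.49), and of 11 antigen presentation genes 7 rose, also adjusted over the list alone, with H2-Ab1 up by 1.82 (SE 0.29). Without the 5 libraries with high Rn7sk 1 interferon gene was called, and with the organ covariates 2 were (medians 0.65 and 0.52). The camera adjusted p of these lists were 5.8e-05 and 8.49e-08 (adjusted p = 0.276 and adjusted p = 0.124 with an estimated correlation). Of 12 T cell markers 1, Il7r, rose (camera adjusted p = 0.0378, and adjusted p = 0.615 with an estimated correlation), and with the organ covariates the median of 0.49 was -0.03 with 0 called by edgeR. Cd3e, a chain of the T cell receptor complex, had values of 0.955 ± 0.75 and 1.6 ± 0.867 CPM. None of 10 B cell and plasma cell markers was called by edgeR (median -0.26; camera adjusted p = 0.921). At an unadjusted p under 0.05 there was 1, and DESeq2 called 1 and limma on FPKM values 0.

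Of 17 contractile genes 9 fell in knockout aorta, and 13 adjusted over the list alone (median -0.98; camera adjusted p = 2.84e-08, and adjusted p = 0.153 with an estimated correlation). Without the 5 libraries with high Rn7sk the median was -0.73 and 1 gene was called, with the organ covariates it was -0.83 with 3, and in the F set without the 2 libraries that hold intestinal transcripts -1.17 with 0, all chosen after seeing the data. Des, the intermediate filament protein desmin, fell by 1.39 (SE 0.29, edgeR adjusted p = 0.00393), and Tpm2, a tropomyosin of thin filaments, fell by 1.07 (SE 0.25, edgeR adjusted p = 0.00761). Of 12 fatty acid oxidation genes 10 fell, and 12 adjusted over the list alone, and of 14 respiratory chain genes 11 fell, and 14 adjusted over the list alone (medians -1.09 and -0.82; camera adjusted p = 4.38e-09 for each, and adjusted p = 0.112 and adjusted p = 0.124 with an estimated correlation). Acadm, the medium-chain acyl-CoA dehydrogenase, fell by 1.18 (SE 0.23), Hadhb, a subunit of the mitochondrial trifunctional protein, fell by 1.38 (SE 0.31), and Cox5a fell by 0.96 (SE 0.2). Of 12 adipocyte markers 5 fell, and 7 adjusted over the list alone (median -0.83; camera adjusted p = 9.72e-06, and adjusted p = 0.124 with an estimated correlation), and Pck1, which supplies glycerol for fat storage, fell by 2.0 (SE 0.38). Of 12 endothelial markers 6 fell, and 10 adjusted over the list alone (median -0.68; camera adjusted p = 5.71e-06, and adjusted p = 0.124 with an estimated correlation). With the organ covariates 2 adipocyte markers and 1 endothelial marker were called (medians -0.69 and -0.61). Summed, 10 kidney genes ranged from 118 to 2740 CPM in knockout PBS libraries and from 4.72 to 752 CPM in treated knockout libraries. The organ covariates hold no kidney marker. A part of kidney RNA in the fatty acid oxidation, respiratory chain and adipocyte falls was not tested.

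The largest rises in knockout aorta were the myeloid and inflammatory genes Trem1 (6.76, SE 0.87), Cxcl5 (6.48, SE 1.33), Sirpb1a (6.17, SE 0.88), Sirpb1c (5.91, SE 0.87), Cd300lf (5.69, SE 0.71) and Il6 (5.67, SE 1.08). Sirpb1a and Sirpb1c belong to a family of close paralogs, and how the counting split their reads is not given in the sources used here, so that their values are uncertain. The largest falls were Ush1c (-7.01, SE 1.72), Pax8 (-5.89, SE 1.67), Cyp3a11 (-5.53, SE 1.47), Dio1 (-5.35, SE 1.31), S100g (-5.13, SE 1.41) and Aadat (-4.96, SE 1.43), most of which are known from kidney, liver or intestine. Slc34a1, the phosphate carrier of kidney tubules, ranged from 43.9 to 1210 CPM in knockout PBS libraries and from 2.14 to 208 CPM in treated knockout libraries. The calls of Pax8, Aadat, S100g and Cyp3a11 were lost on leaving out any 1 of 6, 6, 4 and 3 libraries, with adjusted p up to 0.0724, 0.0784, 0.0688 and 0.0644. All 4 were lost without replicate 2 or 3 of the treated plain set or replicate 3 of the treated F set, and all but Cyp3a11 without replicate 3 of the PBS plain set. Pax8 was also lost without replicate 2 of either F group, and Aadat without replicate 1 of either F group.

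The test called 418 genes in the plain set (399 higher, 19 lower) and 1605 in the F set, and the fold changes of the sets correlated at 0.32 over all tested genes. The count was 1703 without replicate 2 of the treated plain set and 1816 with intestinal and pancreatic marker levels as covariates. It was 440 (103 higher, 337 lower) in the F set alone without the 2 libraries that hold intestinal transcripts, and these last 2 analyses were chosen after seeing the data.

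The third comparison set knockout against wild type aorta under PBS. No gene passed the edgeR test at an adjusted p under 0.05 (smallest adjusted p = 0.18), 954 genes had an unadjusted p under 0.05 where 1231 are expected by chance, and DESeq2 called 88 genes (68 higher, 20 lower). The count was 1 without replicate 1 and 5 without replicate 3 of the wild type plain set. Myh11, the myosin heavy chain of smooth muscle, Acta2, smooth muscle actin, the collagen gene Col1a1 and Cd68 were among the genes not called. Of 12 clock genes 2 were higher and 8 lower in knockout adjusted over the list alone (median -1.5; camera adjusted p = 2.92e-06, and adjusted p = 0.231 with an estimated correlation). Arntl had 9.63 ± 12.8 CPM in wild type and 29.7 ± 10.3 CPM in knockout libraries (SD, n = 6; log2 fold change 2.21, SE 0.38, edgeR adjusted p = 0.18), and Clock differed by 0.43 (SE 0.26, edgeR adjusted p = 1). The camera test called 18 lists with its preset correlation and 0 with an estimated correlation, among them lower adipocyte and fatty acid oxidation genes (medians -0.57 and -0.44; camera adjusted p = 1.17e-07 for each, and adjusted p = 0.264 and adjusted p = 0.342 with an estimated correlation). Without the 5 libraries with high Rn7sk these medians were -0.07 and -0.17, while that of the clock genes was -1.39.

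The fourth comparison asked how treated knockout aorta differed from treated wild type aorta. Knockout libraries held more transcript of contractile, elastic fibre and some matrix genes and less of B cell, adipocyte and fatty acid oxidation genes, while macrophage, cytokine and cell cycle lists were not called. Camera called the T cell, neutrophil and nerve lists lower, though edgeR called none of their genes and no list kept its call with an estimated correlation. In all 1510 genes differed, 1049 higher and 461 lower in knockout (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 6 per group). The count of calls depended on single libraries and on the analysis, and transcripts of other organs differed between the same libraries.

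Of 17 contractile genes 11 were higher in knockout, and 14 adjusted over the list alone (median 1.26; camera adjusted p = 4.19e-11, and adjusted p = 0.273 with an estimated correlation). Smtn was at 212 ± 71.3 CPM in wild type and 506 ± 72.7 CPM in knockout libraries (log2 fold change 1.26, SE 0.22, edgeR adjusted p = 0.00572), and Myl9 at 472 ± 192 and 1380 ± 441 CPM (1.55, SE 0.33, edgeR adjusted p = 0.0112). Tpm2 was higher by 1.13 (SE 0.25) and Kcnmb1, a subunit of the smooth muscle potassium channel, by 1.34 (SE 0.29). The mean log2 CPM over the list lay between 5.73 and 7.66 in the 6 wild type libraries and between 7.91 and 8.85 in the 6 knockout libraries. The lowest, replicate 1 of the wild type F set, held 22130 CPM of the hemoglobin gene Hbb-bs against 559.3 and 221.9 CPM in the other replicates, and without it the list median was 1.01 with 10 genes called. Of the wild type libraries, replicates 1 and 3 of the F set (5.73 and 7.63) held at most 1.83 CPM of the 5 summed intestinal genes. Without the 5 libraries with high Rn7sk the list median was 1.19, with the organ covariates 1.73, and in the F set without the 2 libraries that hold intestinal transcripts 1.56, with 10, 0 and 0 genes called.

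**Figure D3:**
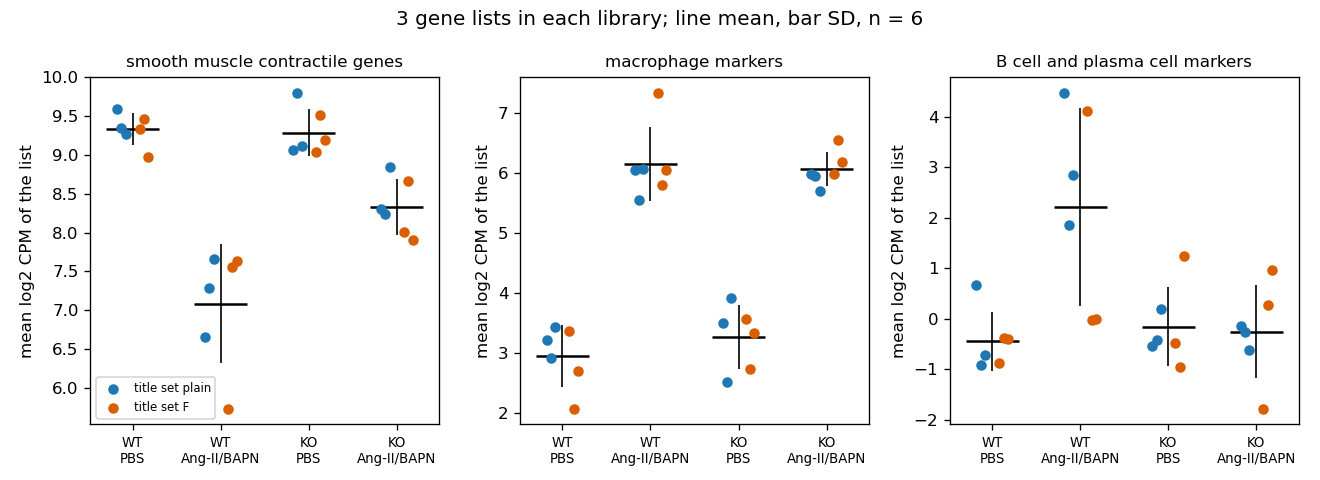
Mean log2 CPM over the contractile, macrophage and B cell lists in each of the 24 libraries, by genotype and treatment; lines are group means and bars 1 SD (n = 6). Treated wild type libraries lie between 5.73 and 7.66 for the contractile list and treated knockout libraries between 7.91 and 8.85.

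Of 19 elastic fibre genes 8 were higher in knockout, and 12 adjusted over the list alone (median 0.75; camera adjusted p = 2.22e-05, and adjusted p = 0.273 with an estimated correlation). Ltbp3, which binds latent transforming growth factor β in the matrix, was higher by 0.84 (SE 0.18, edgeR adjusted p = 0.0116) and Loxl1, a lysyl oxidase of elastic fibres, by 1.35 (SE 0.29, edgeR adjusted p = 0.0124). Of 15 collagens 3, Col6a1, Col6a2 and Col6a3, which together form collagen VI, were higher by 0.77 (SE 0.22), 0.96 (SE 0.25) and 0.94 (SE 0.26), and 8 passed adjusted over the list alone (median 0.47; camera adjusted p = 0.000621, and adjusted p = 0.568 with an estimated correlation). Of 12 fibroblast markers 3 were higher, and 4 adjusted over the list alone (median 0.61; camera adjusted p = 0.000152, and adjusted p = 0.273 with an estimated correlation). These were Dpt at 159 ± 44.7 and 615 ± 423 CPM (1.93, SE 0.3, edgeR adjusted p = 0.00485), Clec3b (2.25, SE 0.53) and Pi16 (1.47, SE 0.37). Of 25 matricellular and fibrosis genes 3 were higher, and 4 adjusted over the list alone (camera adjusted p = 0.121), namely Ccn5 (1.65, SE 0.25), Tgfb3 (1.21, SE 0.24) and Ccn2 (1.17, SE 0.31). Of 19 proteases 2 were higher, and 5 adjusted over the list alone (camera adjusted p = 0.263), namely Mmp23 (1.25, SE 0.24) and Adamts8 (1.05, SE 0.3). Mgp, an inhibitor of vessel calcification, was higher by 1.41 (SE 0.29). Of the Wnt list Nkd1 and the secreted Wnt antagonist gene Sfrp2 were higher by 1.28 (SE 0.24) and 2.11 (SE 0.4), while Lef1 and Tcf7, transcription factors of the pathway that T cells also make, were lower by -1.86 (SE 0.52) and -1.55 (SE 0.46). With the organ covariates the elastic fibre, collagen, fibroblast, matricellular and protease medians were 0.99, 0.92, 1.18, 0.05 and -0.25 with 0 genes called by edgeR. Without the 5 libraries with high Rn7sk 5 elastic fibre genes, 0 collagens and 2 fibroblast markers were called (medians 0.52, 0.39 and 0.5). The calls of Col6a1, Col6a2, Col6a3, Ccn2, Adamts8, Clec3b, Pi16, Lef1 and Tcf7 were lost on leaving out any 1 of 2 to 9 treated libraries. Without replicate 1 of the wild type plain set their adjusted p were 0.115, 0.0766, 0.0877, 0.0864, 0.104, 0.0533, 0.069, 0.118 and 0.145. On leaving out replicate 1 of the knockout F set they were 0.116, 0.0793, 0.0571, 0.068, 0.0789, 0.0841, 0.0909, 0.0998 and 0.125.

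Of 10 B cell and plasma cell markers 6 were lower in knockout, and 10 adjusted over the list alone (median -2.95; camera adjusted p = 1.51e-06, and adjusted p = 0.273 with an estimated correlation). The median was -1.68 without replicate 1 of the wild type F set, where 0 of the 10 genes were called by edgeR. It was -2.73 with 1 gene called without the 5 libraries with high Rn7sk, and -5.72 with 0 called with the organ covariates. Cd79b, a signalling chain of the B cell receptor, was at 9.49 ± 9.92 CPM in wild type and 1.22 ± 0.674 CPM in knockout libraries (log2 fold change -2.97, SE 0.68, edgeR adjusted p = 0.0158), and Ms4a1 at 11.1 ± 13.6 and 0.688 ± 0.353 CPM (edgeR adjusted p = 0.0167). Without replicate 1 of the wild type plain set or replicate 1 of its F set the adjusted p was 0.0546 or 0.0541 for Cd79b and 0.0545 or 0.0746 for Ms4a1, which also lost its call without replicate 2 of the knockout plain set or replicate 1 of its F set (0.0532 and 0.0576). The mean log2 CPM over the list was 4.47, 1.86 and 2.84 in the wild type plain set, where the 5 summed intestinal genes reached 188, 211 and 110 CPM. It was 4.12, -0.02 and -0.01 in the wild type F set, where these genes reached 1.83, 75 and 0.3 CPM, and between -1.78 and 0.96 in treated knockout libraries. Of 12 T cell markers 0 were called by edgeR, 6 had an unadjusted p under 0.05, and DESeq2 and limma on FPKM values called 1 each (median -1.17; camera adjusted p = 0.00254, and adjusted p = 0.587 with an estimated correlation). The T cell median was -0.76 without replicate 1 of the wild type F set and -2.99 with the organ covariates. Cd3e had 3.95 ± 2.43 CPM in wild type and 1.6 ± 0.867 CPM in knockout libraries. No macrophage marker or cytokine gene was called by edgeR, DESeq2 or limma on FPKM values, and 0 had an unadjusted edgeR p under 0.05 (medians -0.08 and -0.23; camera adjusted p = 0.644 and 0.332). With the organ covariates the macrophage, cytokine and cell cycle medians were -1.2, -2.43 and -1.62, with 0 genes called. The organ levels themselves differ between the treated genotypes, so that covariate medians do not show a genotype difference apart from organ RNA. Without replicate 1 of the wild type F set the medians of these lists were 0.23, 0.04 and 0.25. The neutrophil list was lower (median -1.01; camera adjusted p = 0.0326, and adjusted p = 0.587 with an estimated correlation), with a median of -0.18 without that library. Of its 10 genes edgeR called 0, 1 had an unadjusted p under 0.05, and DESeq2 called 0 and limma on FPKM values 1. The nerve and Schwann cell list was lower (median -2.02; camera adjusted p = 0.00194, and adjusted p = 0.587 with an estimated correlation). Of its 10 genes edgeR called 0, 5 had an unadjusted p under 0.05, and DESeq2 called 3 and limma on FPKM values 0. The same 3 tests called none of 20 cell cycle genes, of which 0 had an unadjusted edgeR p under 0.05. Cd68 was at 82 ± 75.7 and 54.1 ± 17.8 CPM, and Il1b at 32.6 ± 19.3 and 26.4 ± 18 CPM in wild type and knockout.

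Of 12 adipocyte markers 6 were lower in knockout, and 7 adjusted over the list alone (median -0.85; camera adjusted p = 1.6e-05, and adjusted p = 0.273 with an estimated correlation). Lpl, lipoprotein lipase, was at 692 ± 218 and 319 ± 101 CPM (log2 fold change -1.13, SE 0.22, edgeR adjusted p = 0.00823), and Pparg, the main transcription factor of fat cells, lower by -1.16 (SE 0.25). Prdm16 of the brown adipocyte list was higher by 1.27 (SE 0.24). Of 12 fatty acid oxidation genes 7 were lower, and 10 adjusted over the list alone (median -0.92; camera adjusted p = 1.08e-07, and adjusted p = 0.273 with an estimated correlation). Of the respiratory chain list Sdha and Uqcrc2, of the glycolysis and hypoxia list Bnip3 and Egln3, and of the interferon list Ifi44 and Rsad2 were lower. Of 12 immediate early genes Ier2 and Egr1 were higher (0.87, SE 0.19, and 0.86, SE 0.24), and 6 adjusted over the list alone. The camera adjusted p of these 4 lists were 0.00109, 0.00401, 0.00841 and 0.00254 (adjusted p = 0.587, adjusted p = 0.568, adjusted p = 0.645 and adjusted p = 0.568 with an estimated correlation). With the organ covariates the medians of the adipocyte, fatty acid oxidation, respiratory chain, glycolysis, interferon and immediate early lists were -0.65, -1.17, -0.82, -0.93, -2.19 and 0.99, with 0 genes called by edgeR. These covariates hold no liver or kidney marker. The respiratory chain and glycolysis medians of -0.43 and -0.4 were -0.22 each without replicate 1 of the wild type F set. Except for Bnip3 and Ier2, these genes lost their calls on leaving out any 1 of 8 to 10 treated libraries. Without replicate 1 of the knockout F set the adjusted p of Sdha, Uqcrc2, Egln3, Egr1, Ifi44 and Rsad2 were 0.103, 0.12, 0.112, 0.108, 0.11 and 0.12.

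The largest differences by the naming rule were mostly in genes of digestive organs. Higher in knockout were Pnliprp1, a pancreatic lipase relative (no count in wild type and 60.4 ± 86.4 CPM in knockout libraries; edgeR adjusted p = 0.0223), and the pancreatic enzyme genes Cpb1 (5.01, SE 0.9) and Ctrl (4.53, SE 1.01). Summed, these 3 genes reached 588, 727 and 84 CPM in the treated knockout plain set and at most 13 CPM in any other treated library. The other 3 of the 6 largest rises were not of this kind: the atrial myosin gene Myh6 (2.88, SE 0.68), the fibulin gene Fbln7 (2.79, SE 0.52) and Slc6a7, a proline transporter (2.76, SE 0.6). Lower in knockout were Clca1, a product of goblet cells (16.6 ± 17.4 CPM in wild type and no count in knockout libraries; edgeR adjusted p = 0.0157), Agr2 (-8.99, SE 1.83), Cps1 (-8.86, SE 2.24), Car1 (-8.79, SE 1.77), Lypd8 (-8.56, SE 1.98) and Cyp2c55 (-8.48, SE 1.53), all known from intestine, colon or liver. Of 10 further intestinal genes 5 and of 10 liver genes 8 were lower in knockout (medians -5.2 and -3.86), while no pancreatic or kidney gene of 10 each was called by edgeR (medians 7.41 and -0.95). At an unadjusted p under 0.05 these were 8 and 1 genes, and DESeq2 called 9 and 0 and limma on FPKM values 10 and 0. Of these lists 1 intestinal, 7 liver, 10 kidney and 0 pancreatic genes exceeded 1 CPM in the median library. Without replicate 2 of the wild type F set the adjusted p was 0.0589 for Clca1 and 1 for Agr2. Without replicate 1 of the wild type plain set or of the knockout F set it was 0.052 or 0.0759 for Pnliprp1 and 0.0537 or 0.0987 for Myh6. Cps1 lost its call on leaving out any 1 of 7 libraries (adjusted p up to 0.0847, without replicate 1 of the knockout F set) and Lypd8 on leaving out any 1 of 5 (up to 0.0738, the same library). These were replicates 1 to 3 of the knockout plain set, 1 of the knockout F set and 2 of the wild type F set for both, and for Cps1 also 1 of the wild type plain set and 2 of the knockout F set.

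**Figure D4:**
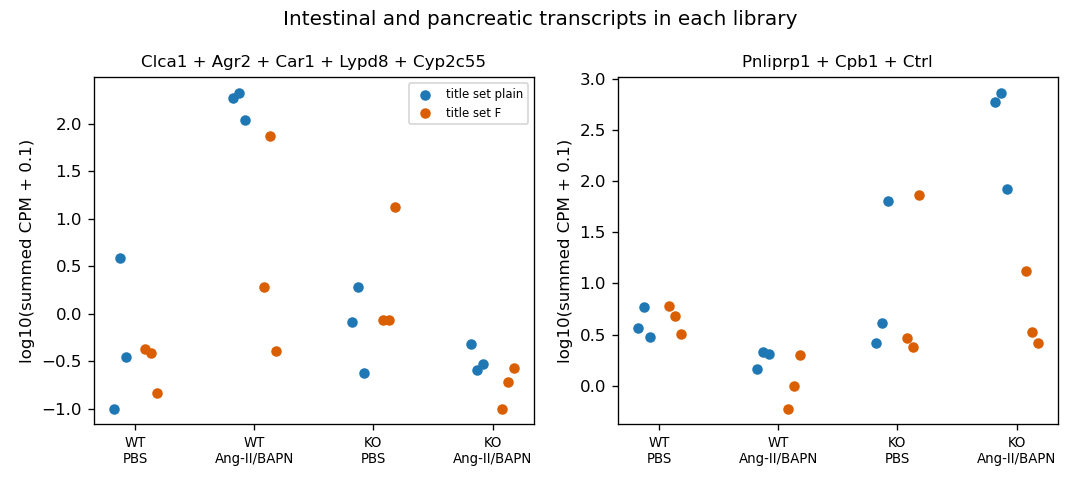
Summed CPM, as log10(sum + 0.1), of Clca1, Agr2, Car1, Lypd8 and Cyp2c55 and of Pnliprp1, Cpb1 and Ctrl in each of the 24 libraries. The intestinal sum is high in 4 of the 6 treated wild type libraries (75 to 211 CPM) and the pancreatic sum in the 3 treated knockout libraries of the plain set (84 to 727 CPM).

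The test of this comparison called 2 genes in the plain set and 36 in the F set alone, and the fold changes of the sets correlated at 0.51 over all tested genes. The count was 651 or 813 without replicate 1 or 2 of the wild type plain set, 836, 751 or 905 without replicate 1, 2 or 3 of the knockout plain set and 658 without replicate 1 of the knockout F set. It was 0 when edgeR was fitted to the 12 treated libraries alone (5347 genes at an unadjusted p under 0.05) against 3230 and 2397 with DESeq2 on all and on the treated libraries, and 5 with the organ covariates. The split of 1049 higher and 461 lower became 497 and 622 on deposited FPKM values with limma, 1806 and 1424 with DESeq2 and 1168 and 1229 with DESeq2 on the treated libraries.

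The fifth comparison asked whether the response to Ang-II/BAPN differed between genotypes. No gene passed the edgeR test of the interaction (smallest adjusted p = 0.111), 3132 genes had an unadjusted p under 0.05, DESeq2 called 599 genes (252 higher, 347 lower) and limma on FPKM values 81 (4 higher, 77 lower). The camera test with its preset correlation called 9 of 30 lists, and 0 with an estimated correlation. The contractile list fell less in knockout (median 1.26; camera adjusted p = 8.29e-12, and adjusted p = 0.576 with an estimated correlation), with 13 of 17 genes past the threshold adjusted over the list alone. Myh11 and Acta2 had interaction values of 1.5 (SE 0.53, edgeR adjusted p = 0.226) and 1.26 (SE 0.46, edgeR adjusted p = 0.244). The B cell list, which rose in wild type and was not called in knockout, had a lower response in knockout (median -3.22; camera adjusted p = 2.33e-06, and adjusted p = 0.576 with an estimated correlation), with 8 of 10 genes past the threshold adjusted over the list alone, and Ms4a1 had a value of -4.47 (SE 1.22, edgeR adjusted p = 0.142). The B cell median was -1.9 without replicate 1 of the treated wild type F set. The T cell list differed likewise (median -1.91; camera adjusted p = 1.52e-05, and adjusted p = 0.576 with an estimated correlation). Cthrc1 had an interaction value of -1.48 (SE 0.56, edgeR adjusted p = 0.267). Leaving out replicate 3 of the treated wild type F set gave 89 genes, replicate 1 of that set 3, and replicate 2 of the knockout PBS plain set 1.

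The last comparisons set the F set against the plain set. No gene differed between them in its response to treatment (edgeR, smallest adjusted p = 0.271; 1744 genes at an unadjusted p under 0.05; DESeq2 374 genes, 34 higher and 340 lower) or in its genotype difference (edgeR, smallest adjusted p = 0.639; 1813 genes at an unadjusted p under 0.05; DESeq2 53 genes, 13 higher and 40 lower). For the response, leaving out replicate 3 of the treated wild type F set gave 4 genes, and replicate 2 or 3 of the treated knockout plain set 1 gene each. For the genotype difference, leaving out replicate 3 of the treated wild type F set gave 1 gene.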

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

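The tests on organ transcripts, on an animal's time of day and a lasting genotype effect for the clock genes, and on the 5 libraries with high Rn7sk were chosen after the result was seen. Camera called the gene lists below for a difference between effects with its preset correlation, and none of the 9, 15 and 10 lists of the 3 differences kept its call with an estimated correlation. Checks of total count, mitochondrial share and Cthrc1 level for single libraries far from the others of their genotype and treatment found none in 12 groups of values. These checks did not cover other genes, and replicate 1 of the treated wild type F set stands apart in Hbb-bs (22130 CPM against 559.3 and 221.9 CPM in its replicates), as does replicate 2 of the treated knockout F set (8381 CPM).

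The interaction of genotype and treatment was called for contractile genes (median log2 difference 1.26), clock genes (1.17), fibroblast markers (0.6) and elastic fibre genes (0.59), whose response lay higher in knockout. It was called lower in knockout for B cell and plasma cell markers (-3.22, and -1.9 without the former library), T cell markers (-1.91), interferon-stimulated genes (-0.67), sex-linked genes (-0.59, and 0.01 on FPKM values) and fatty acid oxidation genes (-0.51, and -0.27 without the former library). Chance could not be excluded for the interaction across genes, since 8 of 60 splits of the libraries gave as many genes at an unadjusted p under 0.05 (real 3132, highest other 5435).

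The response to Ang-II/BAPN was called higher in the F set than in the plain set for red blood cell markers (2.8, and 0.86 without the former library), neutrophil markers (1.74, and 1.93 without 3 genes that a group lacks), macrophage markers (0.85), cell cycle genes (0.75), collagens (0.7), sex-linked genes (0.67, and -0.21 on FPKM values), elastic fibre genes (0.62), matricellular and fibrosis genes (0.52) and proteases (0.5). It was called lower for skeletal muscle markers (-2.08), interferon-stimulated genes (-0.75), antigen presentation genes (-0.69), adipocyte markers (-0.47), fatty acid oxidation genes (-0.31) and respiratory chain genes (-0.25). Without the same library the medians were 0.56 for macrophage markers, 0.38 for cell cycle genes, -0.53 for fatty acid oxidation genes and -0.41 for respiratory chain genes. Chance could not be excluded for this comparison across genes (14 of 60 splits, real 1744, highest other 3170).

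The genotype difference was called higher in the F set for B cell and plasma cell markers (1.3), elastic fibre genes (0.51), collagens (0.46), Wnt genes (0.35) and matricellular and fibrosis genes (0.29), and lower for nerve and Schwann cell markers (-2.71), interferon-stimulated genes (-0.49), adipocyte markers (-0.48), endothelial markers (-0.38) and skeletal muscle markers (-0.14). Without replicate 1 of the treated wild type F set the medians were 2.61 for B cell and plasma cell markers, -0.3 for interferon-stimulated genes and 0.02 for skeletal muscle markers, the last with the other sign. Chance could not be excluded for this comparison across genes either (8 of 60 splits, real 1813, highest other 4499).

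Transcripts of digestive organs led the difference between treated genotypes. Of the 4 pairs of an organ and a treated group that reached 10 CPM, 1 differed by over 10-fold between replicates (intestinal genes in wild type, F set). Over treated and PBS groups it was 4 of 7, and the test was narrowed to treated groups after that count was seen. The count cannot decide on a genotype effect shared by the libraries of a group. In the knockout F set the pancreatic pair reached 10 CPM through replicate 1 (13 CPM), where 10 other pancreatic genes summed to 0.181 CPM. In treated knockout libraries these 10 genes summed to 417 to 4230 CPM in the plain set and 0.181 to 0.835 CPM in the F set. This argues against a pancreatic effect common to both title sets. RNA of another organ in some libraries may account for the digestive organ transcripts. Library by library, the named intestinal and pancreatic genes followed the mean of 10 other genes of their organ (median r 0.88 and 0.97 over 24 libraries). Abundant products reached 52.2 CPM for Muc2 and 615 CPM for Cela2a. Of the 1510 genes 91 (6%), and of the 319 that differed at least 8-fold 88 (27.6%), correlated above 0.8 with an organ level, against 2.3% of all tested genes. Whether the organs were touched at dissection or the tissue differs between the genotypes stays open, since the labels do not say how the aortas were taken.

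Between genotypes under PBS, edgeR called 0 of 12 clock genes, limma on FPKM values 0 and DESeq2 7. Camera called the clock list lower in knockout, but not with an estimated correlation (adjusted p = 0.231). Chance was not excluded for this comparison across genes (23 of 60 splits). The mean of clock output genes minus activator genes was lower in knockout by -3.65 (SE 0.9, exact permutation p = 0.005). That p is the smallest that 400 regroupings within title sets can give. The difference was -2.64 in the plain set and -4.65 in the F set. Under Ang-II/BAPN the difference was -0.59 (SE 0.54), which argues against a difference of the same size in treated animals. It cannot decide on a genotype effect on the clock that does not depend on treatment, since the hours of collection are not known. Treated wild type libraries also lay low, between -1.88 and 1.78, where knockout PBS libraries lay between -1.52 and 1.24. Without the libraries with high Rn7sk the difference was -3.03 (SE 1.38), so that it kept its sign and most of its size. The error is wide, and a part of these libraries in the difference is not excluded. The hour of collection cannot be told apart from genotype in PBS animals. Activator and output genes also moved oppositely within groups over the 24 libraries (r -0.64, permutation p = 0.00147, and rho -0.58, permutation p = 0.0035). These permutations ran over all 24 libraries and not within groups, which differ in spread, so that both p may be too small. The r was -0.31 without the 2 libraries farthest from the median. An effect of genotype in untreated animals alone stays open.

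In 5 libraries Rn7sk, a small nuclear RNA, was at 4.82 to 24.8 CPM against at most 1.42 CPM in the other 19, and their mitochondrial share was 17.1 to 31.9% against 9.6 to 23.7%. A single group of the design is argued against as the cause, since 4 of the 8 groups held libraries of both kinds. The class held replicates 2 and 3 of the wild type PBS F set and replicate 2 of each knockout PBS set. It also held replicate 1 of the treated knockout F set. The class thus lay mostly in PBS and F set libraries and is partly confounded with treatment and title set. A difference in library preparation that depends on GC content may account for the class: over 14373 protein-coding genes its fold change followed transcript GC content (rho 0.63 across genes, which are not independent replicates). The class cannot be blamed for the whole difference between treated genotypes, since 722 of the 1510 genes were called again without the 5 libraries. Fold changes also followed GC content across genes in that comparison (rho 0.31), in the wild type response (-0.29), in the knockout response (-0.14) and in the interaction (0.29).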

How the results depend on the processing

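The alternatives on Rn7sk, organ markers, mitochondrial genes, spread per treatment, treated libraries with DESeq2 and the F set alone were chosen after seeing the data, and the others before. Chance is argued against, as far as 60 splits can tell, for the wild type response (1 of 60 splits reached the real 6097, highest other 1802), the knockout response (1 of 60, real 2813, highest other 1434) and the treated genotypes (1 of 60, real 1510, highest other 268). These splits do not weigh how RNA of other organs fell on the libraries. Chance was not excluded under PBS, where 23 of 60 splits gave at least the real 954 genes at an unadjusted p under 0.05. The highest other split gave 6097, and 815 after adjustment where the real one gave 0, several times the real count, which points to a structure of the samples other than genotype.

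With a fold change of at least 2 the counts were 3821, 1929 and 930 for the wild type response, the knockout response and the treated genotypes, which follows from the stricter criterion. DESeq2 gave 88, 3230, 599, 374 and 53 genes for PBS genotypes, treated genotypes, interaction, response by title set and genotype difference by title set. Limma on FPKM values gave 81 for the interaction and 2 for the response by title set. For the treated genotypes the count was 907 without a filter, 543 with the replicate block, 0 with only the 12 libraries compared (smallest adjusted p = 0.0544), 870 without the 5 libraries with high Rn7sk, 868 with the spread per treatment and 2397 with DESeq2 on treated libraries. The Rn7sk covariate gave 5 interaction genes. With the organ covariates the knockout response had 1816 genes, the treated genotypes 5, the interaction 163 and the title set comparisons 2 and 3. These covariates partly follow genotype and treatment, so that such counts and medians cannot be read as corrected for organ RNA. In the F set without the 2 libraries the counts were 984, 440 and 0. Where fewer genes or samples enter by construction, part of the loss follows from that; otherwise the cause was not tested.

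Of the gene lists called by camera, an estimated correlation left 0 of 21, 5 of 21, 0 of 18, 0 of 14 and 0 of 9 in the first 5 comparisons. Under PBS 7 lists were called without the 5 libraries with high Rn7sk and 9 with the organ covariates, which gave 17 for the interaction; the cause was not tested.

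Leaving out 1 library gave 4696 to 6591 genes for the wild type response, 1703 to 3585 for the knockout response (1703 without replicate 2 of the treated plain set), 0 to 5 under PBS, 651 to 2187 for the treated genotypes, 0 to 89 for the interaction and 0 to 4 and 0 to 1 for the title set comparisons. Of the named genes called, 38 of 52 kept their call in every alternative in the wild type response, 11 of 36 in the knockout response and 0 of 48 between treated genotypes. Direction was reversed in 4 of 1415 comparisons of the last: Agr2 at 3.28, Adamts8 at -0.25 and Bnip3 at 0.02 with organ covariates, and Agr2 at 0 in the F set alone, where the libraries that hold it were left out; for the others the cause was not tested. No scaling moved the median of all genes by over 0.08 on the log2 scale.

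The replicate numbers did not pair the libraries: same-numbered libraries correlated at a median of -0.03 in the F set and -0.07 in the plain set, and 4 of 24 correlated best with their own number. The replicate block gave 4857, 1930, 0, 543, 0, 0 and 0 genes and called 20, 22, 16, 14 and 8 lists.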

Other observations

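The tests of sex-linked genes and of Nnt were chosen after the result was seen, and that of the response score before.

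A single score of the response, from genes called in 1 title set and applied to the other, was set against the idea of a smaller response in the knockout. With genes chosen in wild type, treated knockout libraries scored 2.21 ± 0.62 and treated wild type libraries 3.37 ± 0.84 (SD, n = 6; difference -1.16, SE 0.4, exact permutation p = 0.01). With genes chosen in knockout they scored 3.41 ± 1.1 and 3.5 ± 1.64 (difference -0.09, SE 0.54, exact permutation p = 0.875), where a loss in proportion would give -1.2. The prediction of a smaller response, set before as p under 0.05 for both scores, was thus not met. Each score leans toward the genotype in which its genes were chosen, so that the first alone does not show a smaller response in knockout. Genes chosen in wild type can also include those of intestinal RNA in treated wild type libraries. The second score cannot decide on a response that is smaller as a whole, since it leans on 1 library. Replicate 2 of the treated wild type plain set scored 0.8 against 2.92 and 3.17 in its replicates. That library held 3300 CPM of 10 summed kidney genes, against 27.3 and 16.4 CPM in its replicates. The genes applied to the F set were 399 that rose and only 19 that fell in the knockout plain set. All 24 libraries lay on the side of their title set for Xist against 4 Y-linked genes, which is consistent with female animals in the F set and male animals in the plain set, a hypothesis that the labels used here do not settle.

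Nnt, a mitochondrial transhydrogenase, has 2 overlapping entries on GRCm38 chromosome 13 (119335448 to 119408997 and 119335528 to 119408952, minus strand). The second was counted in 11 of 12 knockout libraries and in replicate 2 of the treated wild type plain set and replicate 2 of the wild type PBS F set. In the share of the first, 6 of 12 knockout libraries lay below the lowest wild type library, so that a difference of this share in every library is not borne out. The level of the first entry lay between 5.24 and 20.8 CPM in the knockout libraries. In wild type it lay between 29.7 and 70 CPM, except for replicate 2 of the PBS F set (13.9 CPM), a library with high Rn7sk. Why these levels differ was not tested. No gene separated all 12 knockout from all 12 wild type libraries with PBS and treated libraries pooled (0.018 expected by chance). Genes that respond to treatment can fail this test for that reason alone. Cthrc1 did so, with up to 10.5 CPM in treated knockout and from 1.52 CPM in wild type PBS libraries. Within PBS it separated the genotypes (at most 0.547 CPM in knockout), as it did under Ang-II/BAPN. The test therefore does not decide on genotype differences within a treatment. Replicate 1 of the treated wild type F set held 22130 CPM of Hbb-bs, a hemoglobin gene of red cells, and 919.5 CPM of Acta2.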
